A study of Homo sapiens with 6 samples.

How the data were processed

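Gene expression was measured by RNA sequencing of total RNA from Huh7 cells treated with P-T3H2 (3 libraries) or the control peptide P-T3H2-2A (3 libraries), at 20 µM for 5 days per the labels. The labels name 2 library kits, VAHTS Universal V6 and SMARTER, without tying either to a library, and the series' design text speaks of more groups than the labels give. Samples were grouped by their titles and treatment labels.

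The authors deposited a table of 50868 genes with whole-number gene counts and FPKM values for each library, per the file headers. HISAT2 2.0.4, StringTie 1.3.3b and edgeR are named in the submitters' processing notes, with no role or order and no version for edgeR. Those notes name a mouse genome build, whereas the deposited table lists human Ensembl genes. Of its gene IDs, 50111 are in GENCODE release 29 (GRCh38), and 47499 of these have identical coordinates, so coordinates are given for GRCh38. The annotation used and the strand setting of the counting are not given in the sources used here. The deposited FPKM values equal the deposited counts divided by the library total and 1 length per gene: the length was the same in all libraries, within a relative tolerance of 0.001, for all 13364 genes with at least 20 counts in each. FPKM therefore carried no normalization beyond the totals. Of gene names, 171 are shared by more than 1 ID; tests were run per ID.

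Total counts per library ranged from 17434442 to 21374732, which sets the counting error. Reads carry no molecular identifiers in the sources used here, so floors cover counting error only. A floor of 3 counts over the group was used for a group at 0. No 2 libraries agreed within sampling noise: chi-square per gene was at least 11.6 over genes with at least 20 counts in the pair.

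Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10 and a total of 15, a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment at 0.05, all fixed before the data were examined. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Values are CPM scaled by library total and TMM factor. HNF4A and count shares were also compared by an exact two-sided permutation test over 20 splits. Gene lists fixed before the data were examined (15 on biology, 7 on other cell types and RNA quality, 702 genes, all found) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists, and again with an estimated correlation and with fry. The lists overlap: a gene can stand in more than 1.

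Named genes followed a rule fixed before the data were examined: HNF4A; the 5 genes with the largest fold change in each direction among those past the threshold with a mean of at least 5 CPM and groups that do not overlap, filled up with the genes of smallest p where fewer passed; and the 2 members of smallest p of each biology list. The same rule applied to the fit without the library labelled P-T3H2-2A replicate 3 was added after the data were seen. Some genes that the rule names are not reported here. TRIB3, ALB and AFP, and the genes given as examples of steps in the counts, were chosen after their values were seen.

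Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals without TMM, no low-count filter beyond 1 count, a mean of at least 5 CPM, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 1 FPKM in 3 libraries, and leaving out each library. Added after the data were seen were the library labelled P-T3H2-2A replicate 3 as the sole control, where it is assumed to vary like the P-T3H2 libraries, and removal of a GC and transcript length trend without that library. GC and length came from GENCODE release 29 transcripts and were known for 99.4% of the genes fitted. A tightly stepped gene was defined as one with a mean of at least 10 CPM, a range within each side of at most 0.5 and a gap between the sides of at least 1 on the log2 scale.

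The edgeR procedure was tested on simulated data. With the spread of the labelled comparison (15685 genes), it recovered 60% of genes changed 2-fold and 96% of those changed 4-fold, with 10 false calls of 166. Changes were placed there on genes drawn at random, with no control library lying with the P-T3H2 libraries. These shares are therefore not the power of the labelled comparison itself. For 3 against 2 libraries with the spread of the fit without the library labelled P-T3H2-2A replicate 3 (15988 genes), the shares were 92% and 95%, with 28 false calls of 215. A labelled comparison simulated with 1 of 3 control libraries drawn from the P-T3H2 profile (15833 genes) gave 0 calls. A list lowered in the 3 against 2 simulation (15970 genes) had a camera adjusted p = 3.69e-76 and, with an estimated correlation, an adjusted p = 0.00384, with 0 other lists called. Genes were drawn independently there, so it could not test whether the preset correlation is high enough for real lists.

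Explanations weighed in the closing section had written criteria. For a wrong label on the library labelled P-T3H2-2A replicate 3 the criterion was the number of genes called. A further criterion on the number of gene lists called, added after those counts had been seen, left the explanation undecided and was dropped, because the list tests of single libraries called 0 biology lists with an estimated correlation. Principal components were computed on log2 CPM, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.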

Results

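RNA sequencing was carried out on 6 libraries of Huh7 cells, a human hepatocellular carcinoma line, treated at 20 µM for 5 days with a cell-permeating peptide, P-T3H2, or with the control peptide, P-T3H2-2A. Each group held 3 libraries. Total gene counts were 17434442, 20200885 and 21228458 in P-T3H2-2A replicates 1, 2 and 3, and 21374732, 20780648 and 21204072 in P-T3H2 replicates 1, 2 and 3. Between 21815 and 22968 genes were detected per library. The labels did not say whether replicates were separate cultures, so p-values measured only the spread between these samples, which may be technical.

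The comparison of P-T3H2 with P-T3H2-2A addressed how gene expression in hepatoma cells responds to a peptide described as stabilising the HNF4α protein. As labelled, LRRC8D, a subunit of volume-regulated anion channels, rose 3.00-fold, from 21.6 ± 0.429 CPM (SD, n = 3) with P-T3H2-2A to 64.7 ± 1.08 CPM (SD, n = 3) with P-T3H2 (ENSG00000171492, chromosome 1, 89821014 to 89936611, GRCh38). Its log2 fold change was 1.58 with a standard error of 0.0791 (edgeR, adjusted p = 0.00619). The library labelled P-T3H2-2A replicate 3 lay with the P-T3H2 libraries for most genes: RANBP3L, a Ran-binding protein of the nuclear transport machinery, stood at 0.462 and 0.346 CPM in P-T3H2-2A replicates 1 and 2, at 77.2 CPM in replicate 3 and at 87.0, 70.1 and 75.9 CPM in the P-T3H2 libraries. Without the library labelled P-T3H2-2A replicate 3, RANBP3L rose 191-fold with P-T3H2, from levels near the floor. The fibrinogen beta chain gene FGB fell 3.97-fold in that comparison. As labelled RANBP3L was 2.97-fold higher and FGB 3.00-fold lower, and neither passed in edgeR.

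LRRC8D was the 1 gene called of 15946 tested by edgeR at a false discovery rate of 0.05. At an unadjusted p under 0.05 there were 2874 genes, against 797 expected by chance; splits that trade the library labelled P-T3H2-2A replicate 3 for P-T3H2 replicate 1, 2 or 3 gave 1558, 3428 and 1445. DESeq2 called 117 genes, 34 higher and 83 lower, and of at least 2-fold 19 higher and 47 lower. This lean to lower genes came from DESeq2, which was not run without the library labelled P-T3H2-2A replicate 3. In edgeR without that library, most calls of at least 2-fold were higher. Leaving out the library labelled P-T3H2-2A replicate 3 gave 7390 calls of 16281 genes, 3686 higher and 3704 lower with P-T3H2, of which 1721 changed at least 2-fold (1156 higher, 565 lower). With a GC and length trend removed from that fit there were 7461 calls, 3052 higher and 4409 lower, so the balance of directions depended on this step. The step also re-centred each library on its mean log2 ratio, so the shift in directions cannot be credited to GC and length alone. Leaving out any other library gave between 0 and 4 calls, and with that library as the sole control there were 62 (732 genes at an unadjusted p under 0.05, against 842 expected by chance). Each P-T3H2 library set against the others of these 4 gave 57, 56 and 59 calls, about as many. The biological coefficient of variation was 0.209 with all libraries and 0.122 without that library. Values without the library labelled P-T3H2-2A replicate 3 are therefore given beside the labelled values of gene lists and fold changes, as the 5-library fit. Counts of list members that passed in this fit are to be read against the 7390 of 16281 genes that passed in it, whatever their list. Leaving out each library was planned, but this emphasis was chosen after the data were seen, so p-values of the 5-library fit are not independent evidence. The simulation of that fit also made more false calls than a rate of 0.05 allows.

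On the first principal component, which held 68.6% of the variance, P-T3H2-2A replicates 1 and 2 scored -60.3 and -58.6. The library labelled P-T3H2-2A replicate 3 scored 27.3 and the P-T3H2 libraries 33.5, 23.8 and 34.3. The second component, with 8.93% of the variance, placed that library at 31.9 and the others between -12.1 and 4.41.

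**Figure D1:**
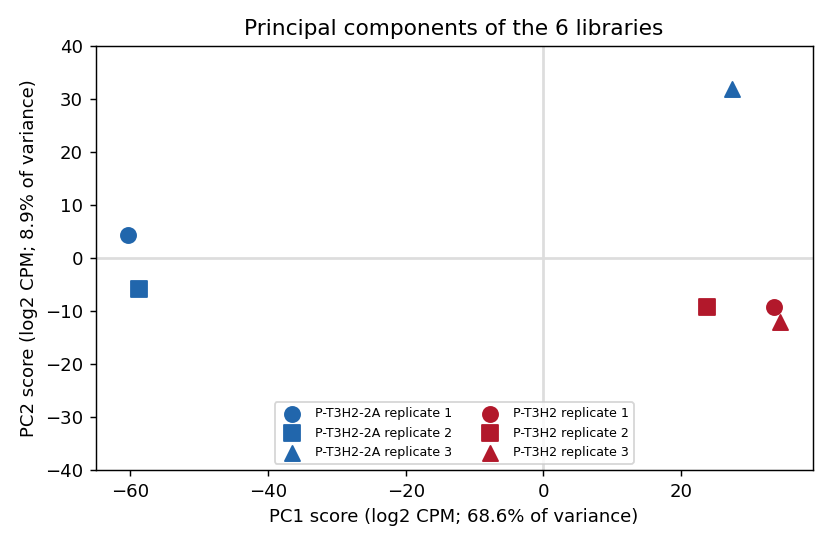
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, 1 point per library, blue for P-T3H2-2A and red for P-T3H2. P-T3H2-2A replicates 1 and 2 sit at -60.3 and -58.6 on the first component, and the library labelled P-T3H2-2A replicate 3 sits at 27.3, among the P-T3H2 libraries.

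Several genes stood on one side in all P-T3H2 libraries and on the other in all P-T3H2-2A libraries without passing the adjusted test in edgeR, a placing that chance gives to 10% of genes. C14orf132 stood at 53.02 ± 1.72 CPM (SD, n = 3) with P-T3H2 and 10.5 ± 2.86 CPM (SD, n = 3) with P-T3H2-2A (log2 fold change 2.34, SE 0.212, adjusted p = 0.111). DPYSL2, a microtubule-binding protein, had a log2 fold change of 1.01 (SE 0.127, adjusted p = 0.275). MAGEA8 and TRIM34 had log2 fold changes of 1.61 and 1.66. COX7A2L, a factor in respiratory supercomplex assembly, stood at 32.4 ± 0.796 CPM (SD, n = 3) against 70.8 ± 7.69 CPM (SD, n = 3), a log2 fold change of -1.13 (SE 0.105, adjusted p = 0.111). TIMM8B, a mitochondrial import chaperone, and the readthrough locus MICOS10-NBL1 had log2 fold changes of -1.17 and -3.32. RIMBP3B had 156 counts over the P-T3H2-2A libraries and 0 over the P-T3H2 libraries, at least 56.0-fold lower with a floor of 3 counts over the group. All of these genes passed in the 5-library fit in the same direction, and DESeq2 called them with all 6 libraries. They had been picked by smallest p from the same libraries, and 7390 of 16281 genes passed in the 5-library fit, so this adds no independent evidence. LRRC8D kept its direction but not its call without P-T3H2-2A replicate 1 (adjusted p = 0.0579), P-T3H2-2A replicate 2 (0.0953), P-T3H2 replicate 1 (0.0705) or P-T3H2 replicate 3 (0.149). Its log2 fold change was 1.57 to 1.60 over all left-out libraries. Genes with a range within each side of at most 0.5 and a gap of at least 1 on the log2 scale numbered 1 in the labelled split, LRRC8D, and 3, 2 and 1 in the splits that trade the library labelled P-T3H2-2A replicate 3 for P-T3H2 replicate 1, 2 or 3. None of the latter 6 genes was both as level and as far apart as LRRC8D, with its wider range of 0.06 and gap of 1.53.

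In the 5-library fit, genes past the threshold with a symbol, a mean of at least 5 CPM and groups that do not overlap were ranked by fold change. The largest increases with P-T3H2 were in RANBP3L, DUOX2, a hydrogen peroxide-producing oxidase, WNT9B, a Wnt ligand, the amino acid transporter SLC6A14 and the anion exchanger SLC4A3. SLC6A14 stood at 160 ± 27.7 CPM (SD, n = 3) with P-T3H2, at 1.79 and 1.83 CPM in P-T3H2-2A replicates 1 and 2, and at 167 CPM in the library labelled P-T3H2-2A replicate 3. The log2 fold changes of RANBP3L, DUOX2, WNT9B, SLC6A14 and SLC4A3 were 7.58, 7.26, 6.55, 6.46 and 6.23, against 1.57, 1.78, 1.66, 1.49 and 1.57 as labelled. In P-T3H2-2A replicates 1 and 2, DUOX2 stood at 0 and 0.0989 CPM, WNT9B at 0.173 and 0.049, and SLC4A3 at 0.289 and 0.148. These levels are near the floor, so the sizes of the DUOX2 (SE 0.753), WNT9B and SLC4A3 rises are uncertain. RANBP3L, at 0.462 and 0.346 CPM in these libraries, was little higher, so the size of its rise is uncertain too. Among the genes so ranked, the largest decreases were in TOMM6, AKR1D1, the Wnt inhibitor DKK1, the acute-phase protein gene ORM1 and the fibrinogen alpha chain gene FGA. Their log2 fold changes were -4.08, -3.85, -3.48, -2.81 and -2.70, against -3.50, -3.35, -2.98, -2.34 and -2.27 as labelled. RIMBP3B and MICOS10-NBL1, which also fell, had a mean below 5 CPM and were not ranked. ORM1 stood at 136.5 and 142.7 CPM in P-T3H2-2A replicates 1 and 2, at 23.1 CPM in replicate 3 and at 19.9 ± 2.75 CPM (SD, n = 3) with P-T3H2. With all 6 libraries none of the 10 ranked genes passed in edgeR (adjusted p between 0.275 and 0.547), while DESeq2 called AKR1D1, DKK1, ORM1 and FGA lower. DESeq2 gave no p-value for RANBP3L, SLC6A14 and SLC4A3. With the library labelled P-T3H2-2A replicate 3 among the controls, the log2 fold changes of the ranked rises shrank more than those of the ranked falls. This follows from averaging, because 1 control near the P-T3H2 level limits the size of any rise, so it is no separate result.

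**Figure D2:**
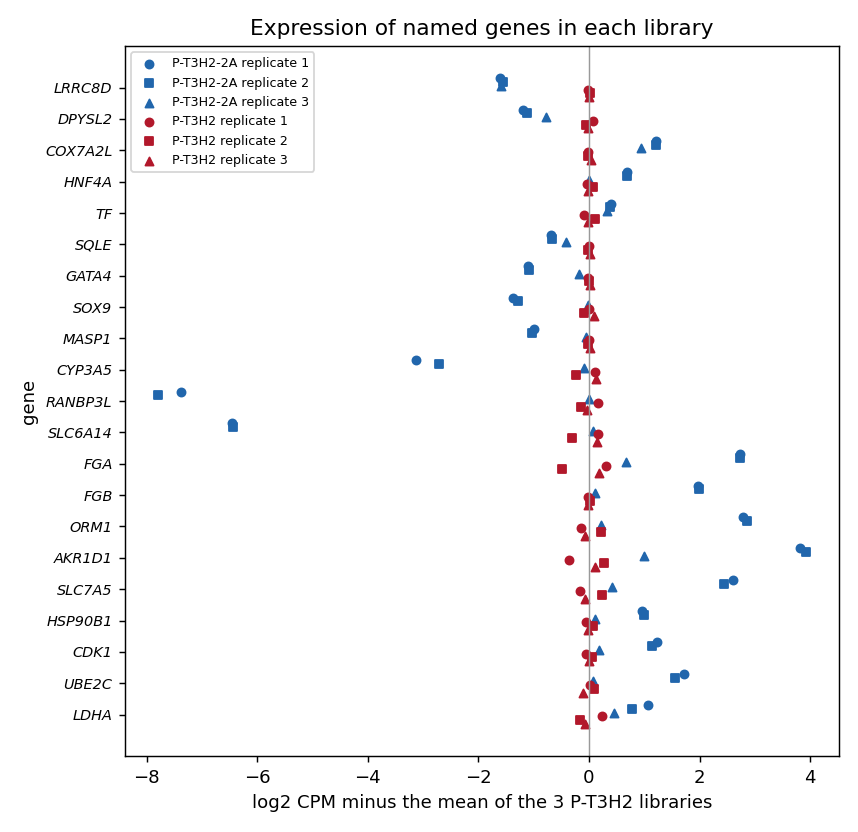
Log2 CPM of 21 genes in each library minus the mean of the 3 P-T3H2 libraries (x axis), 1 point per library, blue for P-T3H2-2A and red for P-T3H2; the 21 were picked for display, after their values were seen, from the genes named by rule. The library labelled P-T3H2-2A replicate 3 (blue triangle) lies with the other P-T3H2-2A libraries for LRRC8D and TF and beside the P-T3H2 libraries for RANBP3L, SLC6A14, FGB and HNF4A.

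HNF4A mRNA, which encodes the nuclear receptor named in the study's title and a main regulator of hepatocyte genes, stood at 76.8 ± 3.10 CPM (SD, n = 3) with P-T3H2 and 107.7 ± 27.0 CPM (SD, n = 3) with P-T3H2-2A (ENSG00000101076, chromosome 20, 44355700 to 44434596, GRCh38). The P-T3H2-2A libraries held 123.4, 123.2 and 76.5 CPM. The log2 fold change was -0.49 (SE 0.190, edgeR adjusted p = 0.275), and an exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest p that 20 splits allow. HNF4A fell by 0.69 on the log2 scale in the 5-library fit (SE 0.0558, adjusted p = 0.000137), and against the library labelled P-T3H2-2A replicate 3 alone the value was 0.0069.

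Of 30 HNF4A target genes tested, none passed in edgeR with all 6 libraries, over all genes or adjusted over the list alone, while DESeq2 called TF lower (adjusted p = 0.0485), and the median log2 fold change was 0.05 (camera adjusted p = 0.80). With P-T3H2-2A replicate 3 left out 7 rose, 8 fell and 15 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.745). Over all genes, 7390 of 16281 passed in that fit. Fry called the list higher there (adjusted p = 0.0221), but it called most biology lists there, higher or lower. The iron carrier transferrin, TF, fell by 0.39 and the fatty acid-binding protein FABP1 fell by 0.80 on the log2 scale in that fit, while CREB3L3, a hepatic transcription factor, and CIDEB, a lipid droplet protein, rose by 0.89 and 0.93. As labelled TF, FABP1, CREB3L3 and CIDEB had values of -0.37, -0.60, 0.59 and 0.64. Of 24 hepatocyte transcription factors, none passed with all 6 libraries in edgeR, under either adjustment, or in DESeq2 (median 0.30, camera adjusted p = 0.0654). Without P-T3H2-2A replicate 3, 11 rose and 5 fell, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.0739). GATA4 rose by 1.09 in that fit, from 84.7 and 85.5 CPM to 181 ± 2.71 CPM (SD, n = 3), with 159 CPM in the library labelled P-T3H2-2A replicate 3, and the oxysterol receptor gene NR1H3 fell by 0.68. Their labelled values were 0.72 and -0.52.

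The list of coagulation, complement and plasma protein genes was lower with P-T3H2 as labelled (51 tested, median log2 fold change -0.22, camera adjusted p = 0.0493; adjusted p = 0.507 with an estimated correlation). None of its members passed in edgeR over all genes or adjusted over the list alone, while DESeq2 called 8 lower, FGA, FGB and TF among them. In the 5-library fit 28 of 53 fell and 13 rose, or 30 and 14 adjusted over the list alone (camera adjusted p = 0.0541). Fibrinogen chains were among those that fell in it: FGB stood at 2963 and 3002 CPM in P-T3H2-2A replicates 1 and 2, at 811 CPM in replicate 3 and at 752 ± 11.1 CPM (SD, n = 3) with P-T3H2. FGA stood at 2174, 2169 and 521 CPM in the P-T3H2-2A libraries and 335 ± 89.2 CPM (SD, n = 3) with P-T3H2. MASP1, a protease of the lectin pathway of complement, rose by 1.01 in the 5-library fit, against 0.62 as labelled. ALB, for albumin, and AFP, for alpha-fetoprotein, chosen after their values were seen, had labelled log2 fold changes of 0.24 and -0.02. ALB rose by 0.42 in the 5-library fit and AFP had a value of -0.02 (adjusted p = 0.827).

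None of the 4 lists of liver metabolism passed as a whole in camera, as labelled or in the 5-library fit. By fry, xenobiotic genes were higher as labelled (adjusted p = 0.0396). In the 5-library fit, fry called most of the biology lists, among them xenobiotic and bile acid genes (higher, adjusted p = 0.00423 and 0.00247). It did not call lipoprotein or gluconeogenesis, amino acid and urea genes there (adjusted p = 0.499 and 0.458). With all 6 libraries, no member of the lipoprotein, bile acid, xenobiotic or gluconeogenesis, amino acid and urea lists passed over all genes in edgeR, while DESeq2 called ABCA1, AKR1D1, SLC51A and HAL lower. Adjusted over the list alone, SLC51A, a subunit of the basolateral bile acid exporter, and AKR1D1, the steroid 5-beta-reductase of bile acid synthesis, fell. The camera adjusted p of these lists was 0.291, 0.505, 0.0611 and 0.80. With P-T3H2-2A replicate 3 left out 5 of 27 lipoprotein genes rose and 9 fell, 9 of 21 bile acid genes rose and 6 fell, 13 of 33 xenobiotic genes rose and 7 fell, and 12 of 32 gluconeogenesis, amino acid and urea genes rose and 14 fell. Adjusted over the list alone the counts were the same except for 7 falling bile acid genes, and the camera adjusted p was 0.479, 0.292, 0.158 and 0.804. The median, mean and test differed in sign for bile acid genes as labelled (median 0.17, mean -0.11, test higher) and for gluconeogenesis, amino acid and urea genes as labelled (0.10, -0.09, higher). They also differed in the 5-library fit for the latter (0.08, -0.14, lower) and for lipoprotein genes (-0.01, 0.03, lower).

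The P450 enzyme gene CYP3A5 stood at 2.89 and 3.86 CPM in P-T3H2-2A replicates 1 and 2, at 23.7 CPM in replicate 3 and at 25.5 ± 3.56 CPM (SD, n = 3) with P-T3H2, and rose by 2.91 in the 5-library fit, against 1.32 as labelled. CYP3A7, CYP2E1 and the sulfotransferase SULT2A1 rose by 2.78, 2.92 and 0.56 in that fit, against 1.36, 1.97 and 0.43 as labelled. Pyruvate carboxylase, PC, KLB, the FGF co-receptor, and ANGPTL4, a lipoprotein lipase inhibitor, rose by 1.20, 0.82 and 1.42, against 0.70, 0.51 and 0.77 as labelled. The urea cycle gene ARG1 fell by 1.00, the histidine-degrading HAL fell by 1.98, and the cholesterol exporter ABCA1 fell by 0.36, against -0.78, -1.61 and -0.39 as labelled. CYP2E1, at 0.116, 0.346 and 0.894 CPM in the P-T3H2-2A libraries and 1.84 ± 0.134 CPM (SD, n = 3) with P-T3H2, and SULT2A1, at 97.7, 96.7 and 123.6 CPM against 143 ± 5.81 CPM (SD, n = 3), did not place the library labelled P-T3H2-2A replicate 3 among the P-T3H2 libraries. TF and ABCA1 also stood apart from P-T3H2 in every P-T3H2-2A library: ABCA1 was at 124.7, 136.9 and 139.9 CPM against 102.3 ± 3.41 CPM (SD, n = 3).

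Cell cycle genes were lower with P-T3H2 as labelled: the median log2 fold change of 55 genes was -0.62 (camera adjusted p = 7.06e-14; adjusted p = 0.523 with an estimated correlation). None passed over all genes in edgeR or DESeq2, and 41 fell adjusted over the list alone in edgeR. Without P-T3H2-2A replicate 3, 50 fell and 1 rose under both adjustments, with a median of -0.85 (camera adjusted p = 2.37e-17; adjusted p = 0.488 with an estimated correlation). The mitotic kinase gene CDK1 stood at 186.3 and 175.3 CPM in P-T3H2-2A replicates 1 and 2, at 89.2 CPM in replicate 3 and at 79.1 ± 2.69 CPM (SD, n = 3) with P-T3H2. UBE2C, a ubiquitin carrier of the anaphase-promoting complex, and the replication genes GINS2 and MCM4 fell by 1.64, 1.01 and 0.73 in that fit, against -1.27, -0.80 and -0.58 as labelled.

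Glycolysis and hypoxia genes were also lower as labelled (29 tested, median -0.30, camera adjusted p = 0.000312; adjusted p = 0.507 with an estimated correlation). None passed over all genes in edgeR, where 8 fell adjusted over the list alone, while DESeq2 called PDK1, LDHA and HK2 lower. In the 5-library fit 18 fell and 3 rose under both adjustments (camera adjusted p = 0.00175; adjusted p = 0.279 with an estimated correlation). Lactate dehydrogenase A, LDHA, stood at 855.9, 700.2 and 558.0 CPM in the P-T3H2-2A libraries and 411 ± 60.5 CPM (SD, n = 3) with P-T3H2. PDK1, HK2 and CA9, for pyruvate dehydrogenase kinase, hexokinase and carbonic anhydrase, fell by 1.45, 1.32 and 1.65 in the 5-library fit, against -1.17, -1.06 and -1.50 as labelled.

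Among fetal liver, progenitor and liver cancer markers none of 24 passed as labelled in edgeR, under either adjustment, or in DESeq2 (median 0.01, camera adjusted p = 0.80). With P-T3H2-2A replicate 3 left out 7 rose and 4 fell under both adjustments (camera adjusted p = 0.475). The median there was -0.0034 while the mean was 0.11 and the test leaned higher. SOX9, a biliary and progenitor transcription factor, and the aldo-keto reductase AKR1B10 rose by 1.33 and 1.90 in that fit, and the chromatin protein gene HMGA2 fell by 0.84, against 0.75, 1.13 and -0.63 as labelled. Among genes of epithelial-mesenchymal transition and invasion none of 26 passed as labelled in edgeR under either adjustment (median 0.11, camera adjusted p = 0.672), while DESeq2 called CDH1 lower (adjusted p = 0.0466). Without P-T3H2-2A replicate 3, 11 rose and 2 fell under both adjustments (camera adjusted p = 0.103). TGFB1 and PLAU, the urokinase gene, rose by 1.46 and 2.65, while the cadherin genes CDH1 and CDH2 fell by 1.01 and 0.43. As labelled TGFB1, PLAU, CDH1 and CDH2 had values of 0.82, 1.24, -0.83 and -0.37.

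For sterol and fatty acid synthesis, SQLE, the squalene epoxidase, rose adjusted over the list alone as labelled, from 208.1, 210.0 and 250.7 CPM to 333 ± 2.90 CPM (SD, n = 3), and none of 37 genes passed over all genes in edgeR, while DESeq2 called SQLE higher (median 0.16, camera adjusted p = 0.133). In the 5-library fit 17 rose and 10 fell under both adjustments (camera adjusted p = 0.157). SQLE rose by 0.67 there, while HMGCS1, an enzyme of the mevalonate pathway, and ACACA, an acetyl-CoA carboxylase, fell by 0.57 and 0.31. The labelled values of SQLE, HMGCS1 and ACACA were 0.58, -0.39 and -0.28.

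None of 36 integrated stress and unfolded protein response genes passed as labelled in edgeR under either adjustment (median -0.22, camera adjusted p = 0.0525), while DESeq2 called SLC7A5 and DDIT4 lower. With P-T3H2-2A replicate 3 left out 19 fell and 9 rose, or 20 and 9 adjusted over the list alone (camera adjusted p = 0.0522). The amino acid transporter SLC7A5 stood at 138.4 and 124.4 CPM in P-T3H2-2A replicates 1 and 2, at 30.7 CPM in replicate 3 and at 23.0 ± 3.55 CPM (SD, n = 3) with P-T3H2. The chaperone genes HSP90B1 and SDF2L1 and the mTORC1 inhibitor DDIT4 fell by 0.97, 1.22 and 0.91 in the 5-library fit, against -0.74, -0.94 and -0.78 as labelled. Within P-T3H2-2A replicates 1 and 2, TRIB3, chosen after its values were seen, differed, at 192.7 and 119.0 CPM.

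None of 29 p53 and apoptosis genes and none of 22 interferon and inflammation genes passed as labelled in edgeR, under either adjustment, or in DESeq2 (medians 0.21 and 0.10, camera adjusted p = 0.0868 and 0.399). Without P-T3H2-2A replicate 3, 11 of 29 rose and 4 fell in the former, or 12 and 4 adjusted over the list alone, and 7 of 24 rose and 3 fell in the latter under both adjustments (camera adjusted p = 0.103 and 0.368). TP53INP1, a p53-induced stress gene, rose by 2.28 in that fit, and GADD45B, PMAIP1 and BTG2 rose by 1.05, 0.90 and 0.48. The labelled values of TP53INP1, GADD45B, PMAIP1 and BTG2 were 1.05, 0.43, 0.64 and 0.50. NFKBIA, the NF-κB inhibitor, and the RNA sensor genes DDX58 and IFIH1 rose by 1.48, 0.90 and 0.58, and TNFAIP3 fell by 0.41. As labelled NFKBIA, DDX58, IFIH1 and TNFAIP3 had values of 0.79, 0.48, 0.52 and -0.34.

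**Figure D3:**
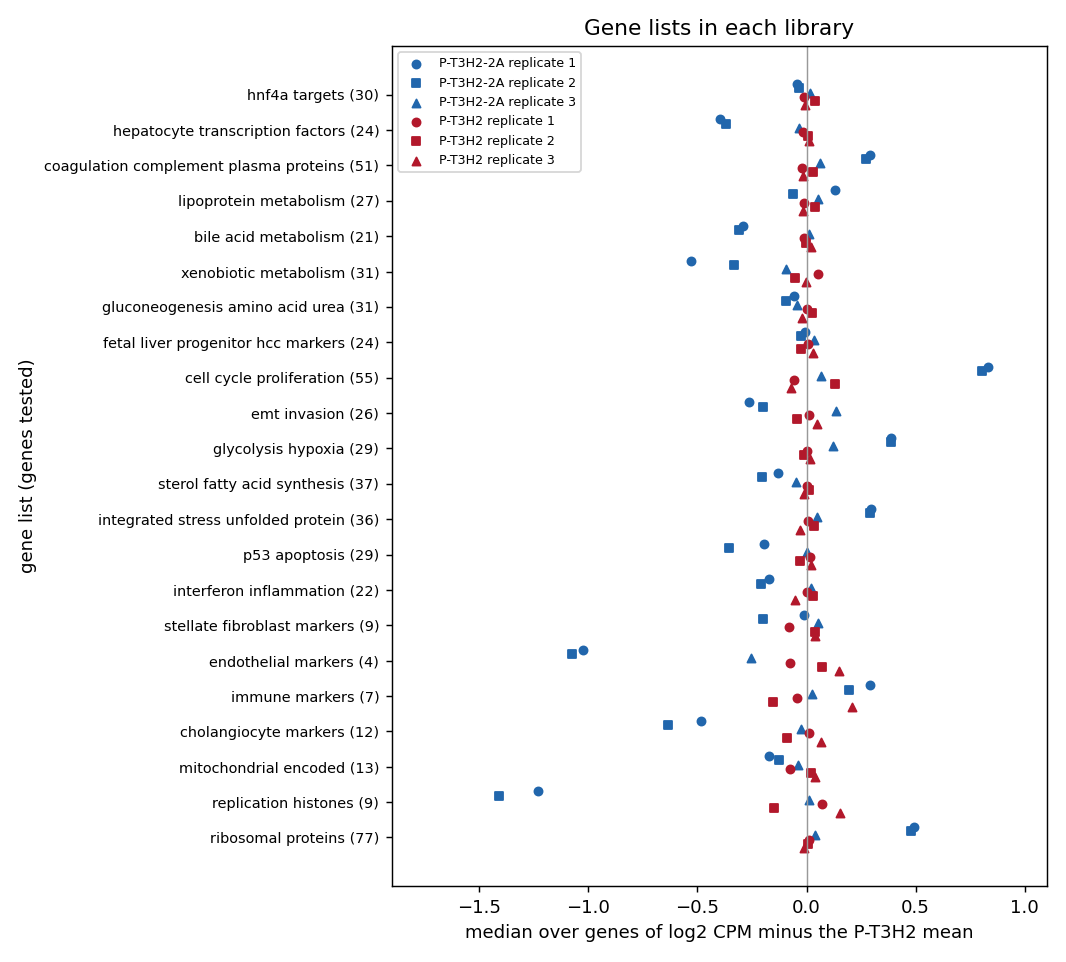
Median over the genes of each list of log2 CPM minus the mean of the 3 P-T3H2 libraries (x axis), 1 point per library, blue for P-T3H2-2A and red for P-T3H2, with the number of genes tested in brackets. For cell cycle genes P-T3H2-2A replicates 1 and 2 lie at 0.83 and 0.80 and the library labelled P-T3H2-2A replicate 3 at 0.07.

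Among the lists used to look for other cell types and RNA quality, ribosomal protein genes were lower with P-T3H2 as labelled (77 tested, median -0.35, camera adjusted p = 7.42e-15; adjusted p = 0.523 with an estimated correlation). Cholangiocyte markers (12 tested, median 0.31) and mitochondrially encoded genes (13 tested, median 0.12) were higher, each with a camera adjusted p = 0.0493 and, with an estimated correlation, adjusted p = 0.536 and adjusted p = 0.556. No member of these lists passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2. In the 5-library fit 66 ribosomal protein genes fell, 67 adjusted over the list alone, 7 cholangiocyte markers rose and 1 fell, and 4 mitochondrially encoded genes rose (camera adjusted p = 6.96e-18, 0.0323 and 0.0442; with an estimated correlation, adjusted p = 0.125, adjusted p = 0.488 and adjusted p = 0.544). Replication histone genes (9 tested) had a camera adjusted p = 0.241 as labelled and 0.110 in the 5-library fit, where 6 rose and 2 fell. Stellate cell and fibroblast markers (9 tested), endothelial markers (4) and immune markers (7 as labelled, 8 in the 5-library fit) had camera adjusted p = 0.80, 0.311 and 0.763 as labelled and 0.411, 0.557 and 0.479 in the 5-library fit, where 3, 2 and 1 rose and 1, 1 and 3 fell. The stellate list had a median of -0.05 and a mean of 0.04 as labelled, with the test leaning higher.

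These shares moved with the same placing of libraries. Mitochondrially encoded genes took 5.998%, 5.987% and 6.91% of counts in the P-T3H2-2A libraries and 6.87%, 7.24% and 7.39% in the P-T3H2 libraries (exact two-sided permutation p = 0.2). Ribosomal protein genes took 3.03%, 2.91% and 2.24% against 2.23%, 2.20% and 2.14% (exact two-sided permutation p = 0.1, the smallest that 20 splits allow). The 10 most abundant genes took 8.86%, 8.85% and 10.1% against 9.84%, 10.3% and 10.2% (exact two-sided permutation p = 0.2), and replication histone genes gave p = 0.2 in the exact permutation test.

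The strand setting of the counting is not given in the sources used here, and TIMM8B, SLC51A, NR1H3, ARG1, GINS2, CA9, CIDEB, ANGPTL4 and TGFB1 overlap an opposite-strand gene of similar or higher level, so their values are uncertain. The same holds for TOMM6, TRIM34, MICOS10-NBL1, CYP3A7 and CYP2E1, which share sequence with an overlapping gene on their own strand, and for RIMBP3B, MAGEA8, CYP3A5 and ORM1, which have close paralogs.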

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

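The sole control of the library labelled P-T3H2-2A replicate 3 and the GC and length correction were added after the data were seen. Calls numbered 1 as labelled, 117 with DESeq2, 3 with limma-voom, 4 without a low-count filter, 2 with limma-trend on log2(FPKM + 1), 62 with the library labelled P-T3H2-2A replicate 3 as sole control and, without it, 7461 (3052 higher, 4409 lower) after the GC and length correction; of at least 2-fold there were 66, 3, 4, 2 and 38. Each P-T3H2 library against the others of these 4 gave 57, 56 and 59 calls, and 33, 35 and 39 of at least 2-fold, about as many as the sole control. Leaving out 1 library gave 0 to 7390 calls and 0 to 1721 of at least 2-fold, the highest without P-T3H2-2A replicate 3. With the replicate block edgeR called 0 genes and 0 of at least 2-fold (3132 at an unadjusted p under 0.05), and LRRC8D had an adjusted p = 0.253. The deviations of same-numbered libraries from their group means correlated at -0.0513, 0.163 and 0.112, and not every library correlated best with its own number. The library labelled P-T3H2-2A replicate 3 lay far from the other controls and weighed on these deviations, so this check could hardly show pairing. Numbers were not taken to pair the libraries. HNF4A ranged from -0.69 to -0.38 over left-out libraries and was 0.0069 with the sole control. Called biology lists numbered 3, and 0 with an estimated correlation, 1 with fry (xenobiotic genes), 5 with the sole control and 2 to 6 over left-out libraries; called check lists numbered 3, and 0, 0, 1 and 1 to 3. With the sole control 9 named genes reversed: SLC6A14 (-0.0591), TOMM6 (1.69), ANGPTL4 (-0.0095), HMGCS1 (0.0485), TP53INP1 (-0.0521), GADD45B (-0.32), NFKBIA (-0.0242), DDX58 (-0.10) and ALB (-0.0564). The direction of the list test also reversed there, with medians given, for HNF4A targets (-0.0078), stellate (-0.0413), fetal (-0.0308), bile acid (-0.0081), EMT (-0.10, adjusted p = 0.016, and adjusted p = 0.556 with an estimated correlation), immune (0.0466) and histone lists (-0.0358). A mean of at least 5 CPM reversed that direction for HNF4A targets (median -0.0098) and gluconeogenesis genes (0.11, where the test leaned lower). Leaving out 1 library also reversed AFP and the test direction of 3 lists: AFP ranged from -0.0838 to 0.0446, and list medians from 0.0426 to 0.0976 (gluconeogenesis), -0.0101 to 0.0244 (fetal) and -0.174 to 0.198 (stellate). The cause was not tested. DESeq2 size factors, library totals and log2(FPKM + 0.1) changed no count by over 1.5 times. Depth limits genes near the floor, such as RIMBP3B, CA9 and, in P-T3H2-2A replicates 1 and 2, RANBP3L, DUOX2, WNT9B, SLC4A3 and CYP2E1.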

Other observations

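Chosen after the results were seen were the tests of a wrong label, of a label swap and of separate preparation, the count of splits for called genes, the GC and length correction, the library labelled P-T3H2-2A replicate 3 as sole control, the comparisons of single libraries below and the comparison of stepped genes with the range and gap of LRRC8D.

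Glycolysis and hypoxia genes had a median log2 level above the P-T3H2 mean in each P-T3H2-2A library, by 0.39, 0.39 and 0.12 in replicates 1, 2 and 3. Against the library labelled P-T3H2-2A replicate 3 alone the list's median was -0.12 (camera adjusted p = 0.000706), while each P-T3H2 library against the others of these 4 gave adjusted p = 0.759, 0.112 and 0.807. Cell cycle genes passed in all 4 of these comparisons (adjusted p = 0.016, 0.000602, 1.00e-08 and 6.62e-06), and their median of -0.06 against that library was smaller in size than those of P-T3H2 replicates 1, 2 and 3, at 0.10, -0.15 and 0.13. These tests used the preset correlation and 1 library on one side, and with an estimated correlation none of the 4 comparisons called a biology list (glycolysis and hypoxia genes against that library, adjusted p = 0.556 with an estimated correlation). The count of called lists, 5 for that library and 1, 1 and 2 for the P-T3H2 libraries, therefore decides nothing.

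P-T3H2-2A replicates 1 and 2 lay apart from the other 4 libraries. A swap with a P-T3H2 library is argued against, since the highest position of a P-T3H2 library, from 0 at their mean to 1 at the mean of P-T3H2-2A replicates 1 and 2, was 0.0753, and a GC or length trend as the whole cause by 7461 calls after its removal, 7358 before and 6671 shared. A single wrong label may account for the placing, as a hypothesis. The labelled split called 1 gene, no more than the highest of the splits trading that library for a P-T3H2 library, at 2. This count cannot decide it: the simulation with 1 of 3 control libraries drawn from the P-T3H2 profile gave 0 calls, so few calls follow whether or not the label is right. On the second principal component the library labelled P-T3H2-2A replicate 3 stood apart, at 31.9 against -12.1 to 4.41 for the others. Separate preparation of P-T3H2-2A replicates 1 and 2 cannot be told apart either, since the labels tie 0 libraries to 1 kit. An effect of P-T3H2 stays open and untested, because it would need the label of P-T3H2-2A replicate 3 to be wrong or its cells to have behaved like treated ones.

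LRRC8D, the single call as labelled, had nearly level values within each group. Steps in the counts of single gene models that follow no group may account for it: among the 3 splits trading the library labelled P-T3H2-2A replicate 3 for a P-T3H2 library, the highest number of tightly stepped genes was 3, against 1 in the labelled split. None of the genes in the other splits was both as level and as far apart as LRRC8D (range 0.06, gap 1.53 on the log2 scale), though ACTR1A was as level (range 0.06, gap 1.13) and DCP2 farther apart (range 0.13, gap 1.69), so the bar counted was looser than LRRC8D's own values. Single libraries showed steps in 4 to 13 genes: MDM4 stood at 30.7 CPM in P-T3H2-2A replicate 1 and 5.46 to 6.98 CPM elsewhere, DAG1 at 347 CPM in P-T3H2 replicate 1 and 48.0 to 56.6 CPM elsewhere, and CREB3L2 at 58.2 CPM in P-T3H2 replicate 3 and 277 to 314 CPM elsewhere. An effect of P-T3H2 on LRRC8D stays open, as its level in the library labelled P-T3H2-2A replicate 3 was that of the other P-T3H2-2A libraries.

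The 10 splits of 6 libraries are too few for a share under 0.05. For called genes, 5 of the 10 splits gave as many as the labelled split (1 gene, highest other 2), and 5 of 10 for calls of at least 2-fold (1, highest other 2). For called biology lists and check lists it was 1 of 10 each (3, highest other 2, in both). Without the library labelled P-T3H2-2A replicate 3, 1 of 10 splits gave as many calls (7390, highest other 3). DESeq2 called 117 genes in the labelled split and 47, 246 and 30 in the splits trading that library for P-T3H2 replicate 1, 2 or 3. The splits that part P-T3H2-2A replicates 1 and 2 gave 15, 8, 6, 3, 11 and 9. Every split that kept these 2 libraries together thus had more calls, labelled or not.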
